A study of Mus musculus with 3 samples.

How the data were processed

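Chromatin immunoprecipitation sequencing (ChIP-seq) was done with a monoclonal rabbit antibody against NBS1 in 2 mouse pre-B cell lines transformed with v-Abl, AH2 and R2K.Artm, and an input library, DNA not selected with an antibody, was sequenced from AH2. NBS1 is a subunit of the MRE11-RAD50-NBS1 complex, which binds the ends of DNA double-strand breaks. Per the labels' protocols, cells were crosslinked in 1% formaldehyde for 5 min, chromatin was sonicated to fragments averaging 250 bp, 5 µg of antibody was used per sample, and sequencing was on an ABI SOLiD platform. The labels give no genotype or treatment for either line. Each of the 3 groups holds 1 library, so no value has a replicate error, no test between groups was run, and no p-value is given.

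The authors deposited the 4 peak lists analysed here; reads and coverage were not used here. Per the submitters' processing notes, Bowtie, MACS 1.4.2 and the mouse build mm9 were used, and the Bowtie version and the control library of each peak call are not given in the sources used here. Per the file headers, the NBS1 lists were made with a fold setting named MFOLD4, and each list comes from 1 library. The fourth list holds AH2 NBS1 peaks after subtraction. Its file title says that R2K.Artm NBS1 and input were subtracted, its header names R2K.Artm NBS1 only, and how this was done is not stated in either. The value of each peak in the deposited files is a score from the authors' peak caller, with a minimum of 50 in every list. MACS of this version usually writes a negative multiple of the logarithm of the peak's p-value there, but the headers do not say so. The score is the authors' own, and it was used here to rank, filter or describe peaks within a list. The scores of intervals found in both AH2 lists were compared only for being equal. The sequencing depth of the libraries is unknown, and a deeper library or another control changes how many peaks are called, so numbers of peaks were not compared as amounts of binding.

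From these lists, intervals were joined in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. An overlap of at least 1 base counted as shared. Shares of peaks carry 95% Wilson intervals (scipy 1.17.1), which cover counting error only and treat peaks as independent, although neighbouring peaks are not. For a count of 0 the limit given is 3 counts of the total. As a description of chance, the peaks of a list were placed at random 1000 times within their chromosome with their widths kept, between the first and the last base that any list covers there. These placements ignore assembly gaps and differences in mappability. Positions are given 1-based in mm9, with 1 added to each deposited start. The interval joins were tested on simulated data: of 2000 simulated peaks, 600 were planted on peaks of another list, and the join found 602 overlaps, as did a direct search.

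The gene table at hand is of build GRCm38, and coordinates were not converted, so peaks carry no gene names and are named by position. The planned comparisons with gene lists, gene annotation, simple sequence repeats and recombination signal sequences needed the mm9 sequence or annotation and were not run. The 6 antigen receptor loci (Igh, Igk, Igl, Tcra/Tcrd, Tcrb and Tcrg) were taken as windows rounded to whole megabases from general knowledge of mm9, so they include some flanking sequence. Each window's count was set beside 10000 random windows of the same length on the same chromosome that did not touch the locus.

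Fixed before the data were examined were the groups, the overlap rule, the windows, the comparisons, the alternatives listed next and the rule for named peaks. That rule names the peaks of the subtracted list in antigen receptor loci, its 10 highest-scoring intervals, and the 5 highest-scoring peaks of each other list. These alternatives were coverage of at least 50% of a peak, a distance of up to 1 kb, a score of at least 100, equal numbers of top-scoring peaks, exclusion of chrY, chrM and unplaced sequences from the overlaps, windows widened by 500 kb, and a clustering distance of 100 kb instead of 10 kb. The equal number taken from each list was 50% of the shorter list, so this alternative is also a score limit. Added after seeing the data were merging of intervals under 10 kb apart, restriction to intervals identical to an AH2 NBS1 peak, exclusion of intervals that overlap an input peak, exclusion of chrY, chrM and unplaced sequences from the antigen receptor shares, and chromosome shares outside the 6 windows. Dense runs were defined, also after seeing the data, as 5 or more intervals of the subtracted list each under 10 kb from the next.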

Results

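NBS1 occupancy was profiled by ChIP-seq in AH2 and R2K.Artm, mouse pre-B cell lines transformed with v-Abl, the oncogene of Abelson murine leukaemia virus, and set against an AH2 input library. The study's title places the question in breaks made by RAG1/2, the recombinase that cuts antigen receptor genes in developing lymphocytes, at loci other than immunoglobulin genes. The design addresses it by comparing NBS1 peaks of AH2 with those of R2K.Artm and input. With 1 library per group there is no replicate error for any value below, and the depth of the libraries is unknown.

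The AH2 NBS1 list held 5201 peaks, the R2K.Artm NBS1 list 3192, the AH2 input list 11903 and the AH2 list after subtraction 1489. The median peak width was 145 bp in R2K.Artm NBS1, 134 bp in AH2 input and 121 bp in the subtracted list, and the middle 50% of AH2 NBS1 peaks were 91 to 140 bp wide. The peaks covered 720 kb, 570 kb, 1958 kb and 194 kb, in the order AH2 NBS1, R2K.Artm NBS1, AH2 input and subtracted list. In the subtracted list, 60 intervals, 4.03%, had a score of at least 100.

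The first comparison asked which NBS1 peaks the AH2 and R2K.Artm lines shared. Of the 5201 AH2 NBS1 peaks, 1705 overlapped an R2K.Artm NBS1 peak, 32.8% (95% interval 31.5 to 34.1%). In the other direction, 1659 of the 3192 R2K.Artm NBS1 peaks overlapped an AH2 NBS1 peak, 51.97% (50.2 to 53.7%). The strongest regions were common to all libraries. The 5 highest-scoring peaks of AH2 NBS1 lay on chromosome 12 at 3109851 to 3110210, on chromosome 2 at 98502310 to 98503159 and 98506380 to 98507505, on chromosome 6 at 103599032 to 103599299 and on chromosome 9 at 35112788 to 35113190. All 5 overlapped peaks of R2K.Artm NBS1 and of AH2 input, and none overlapped the subtracted list. The 5 highest-scoring peaks of R2K.Artm NBS1 were the same 5 regions. The 5 highest of AH2 input were 4 of those regions and a peak on chromosome 4 at 118219636 to 118221378. In each of these lists several peaks tied at a score of 3100, among them all 5 of input, and ties were ordered by position. Random placement of the AH2 NBS1 peaks gave a mean of 8.72 overlaps with R2K.Artm NBS1 and at most 19 in 1000 placements.

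The input library showed how much of each NBS1 list coincided with regions that gained reads without the antibody. AH2 input peaks overlapped 1502 AH2 NBS1 peaks, 28.9% (27.7 to 30.1%), and 1236 R2K.Artm NBS1 peaks, 38.7% (37.0 to 40.4%). Random placement gave at most 26 and 23 overlaps. Of the AH2 NBS1 peaks, 1097 overlapped both other lists, 608 overlapped R2K.Artm NBS1 only, 405 overlapped input only and 3091 (59.4%) overlapped neither. Within the AH2 NBS1 list the median score was 164 for peaks in both other lists, 87.5 for those in R2K.Artm NBS1 only, 70.8 for those in input only and 58.3 for those in neither. In the highest of 10 equal classes of AH2 NBS1 scores, 98.3% of peaks overlapped R2K.Artm NBS1 and 89.4% overlapped input, against 4.99% and 5.37% in the lowest class. The overlap with R2K.Artm NBS1 was 55.3% when only scores of at least 100 were used, so its size depended on the score limit.

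**Figure D1:**
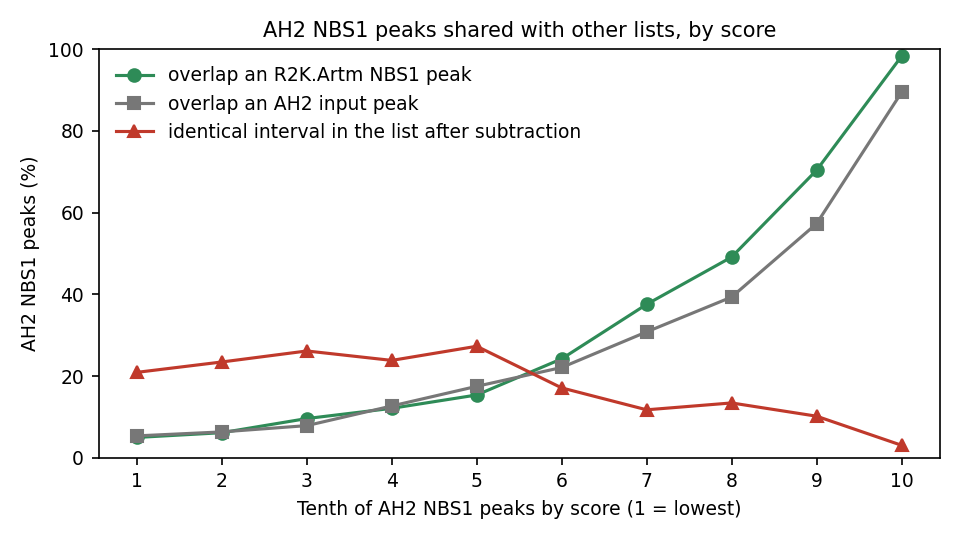
Share of AH2 NBS1 peaks (vertical axis, percent) in each of 10 equal classes of their own score (horizontal axis, 1 is lowest) that overlapped an R2K.Artm NBS1 peak, overlapped an AH2 input peak or recurred as an identical interval in the list after subtraction. Overlap with R2K.Artm NBS1 ran from 4.99% in the lowest class to 98.3% in the highest, while recurrence in the subtracted list was 20.9% in the lowest and 3.08% in the highest.

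The subtracted AH2 list is titled as the AH2 NBS1 peaks left after R2K.Artm NBS1 and input. It was not a subset of the AH2 NBS1 list: 922 of its 1489 intervals, 61.9% (59.4 to 64.4%), were identical to an AH2 NBS1 peak, and the other 567 overlapped none. The deposited score of the 922 identical intervals was equal in both lists, within 0.01, for 64. Of the 1489 intervals, 10 overlapped an R2K.Artm NBS1 peak, 0.672% (0.365 to 1.23%), and 92 overlapped an AH2 input peak, 6.18% (5.06 to 7.52%). Of the 3091 AH2 NBS1 peaks that overlapped neither other list, 836 (27.0%) were in it. The AH2 NBS1 peaks kept in the subtracted list had a median score of 60.01 in the AH2 NBS1 list, and those not kept had 71.01.

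The highest-scoring intervals of the subtracted list lay on several chromosomes, and most coincided with input peaks. The highest was on chromosome 18 at 43135374 to 43135836 (score 1295), followed by 3 adjacent intervals on chromosome 5, at 4053654 to 4054502 (953), 4052384 to 4053094 (709) and 4053115 to 4053633 (514). Next were chromosome 6 at 136951269 to 136951795 (494), chromosome 4 at 118219650 to 118221351 (455) and chromosome 15 at 59973301 to 59973620 (351). The remaining 3 of the top 10 were in immunoglobulin windows: chromosome 12 at 116855118 to 116856009 (320) and 117046844 to 117047317 (235) in Igh, and chromosome 6 at 70672652 to 70673045 (233) in Igk. All 10 were identical to AH2 NBS1 peaks, and 8 overlapped an AH2 input peak. The exceptions were the interval in Igk and the second in Igh. The interval on chromosome 4 was the only one of the 10 that also overlapped an R2K.Artm NBS1 peak. Within the AH2 NBS1 list the Igh intervals ranked low, with scores of 54.6 and 57.2 under that list's median of 67.6, and the Igk interval had 166.

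Antigen receptor loci, where RAG1/2 cuts during V(D)J recombination, were examined next. In the immunoglobulin heavy chain (Igh) window on chromosome 12, which spans 4 Mb, the subtracted list had 105 intervals, 7.05% of the list (5.86 to 8.47%). The same window held 36 AH2 NBS1 peaks, 0.692% (0.500 to 0.957%), 13 R2K.Artm NBS1 peaks, 0.407% (0.238 to 0.696%), and 68 AH2 input peaks, 0.571% (0.451 to 0.724%). The share in the subtracted list was 17.3 times that in R2K.Artm NBS1 and 12.3 times that in AH2 input. By its title those lists were subtracted from it, so these folds do not compare like with like. Its density was 26.2 intervals per Mb, against 0.509 per Mb on the rest of the chromosome, and the fullest of 10000 random windows held 5. Before subtraction, the Igh share of AH2 NBS1 was 1.70 times that of R2K.Artm NBS1 and 1.21 times that of input, and the intervals of these shares overlapped. Each of those 3 lists also exceeded its own random windows in Igh: 36 against at most 14, 13 against at most 12, and 68 against at most 30. Igh peaks were therefore denser than elsewhere on the chromosome without the antibody as well. Of the 105 intervals, 15 overlapped an input peak, a larger share than in the whole subtracted list (92 of 1489, 6.18%). None overlapped an R2K.Artm NBS1 peak, but only 10 of the 1489 did so in the whole list.

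The Igh intervals of the subtracted list were concentrated in dense runs. There were 7 such runs in the window, together 177 kb long, with 77 of the 105 intervals, and only 1 run elsewhere in the genome, on chromosome 9 at 123832768 to 123844718 with 5 intervals. The fullest run, at 116831743 to 116860888 on chromosome 12, had 24 intervals, and the same stretch had 2 AH2 NBS1 peaks, no R2K.Artm NBS1 peak and 3 AH2 input peaks. The next, at 117030859 to 117076373, had 20 intervals beside 1 AH2 NBS1 peak, 1 R2K.Artm NBS1 peak and no input peak. The third, at 114929549 to 114959001, had 11 intervals and no peak of any other list. Of the 105 intervals, 24 were identical to an AH2 NBS1 peak and 81 were in the subtracted list alone among the AH2 NBS1 lists. The 24 made up 2.60% (1.76 to 3.84%) of the 922 identical intervals, and with intervals under 10 kb apart merged the Igh share of the subtracted list was 2.05% (1.42 to 2.95%).

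**Figure D2:**
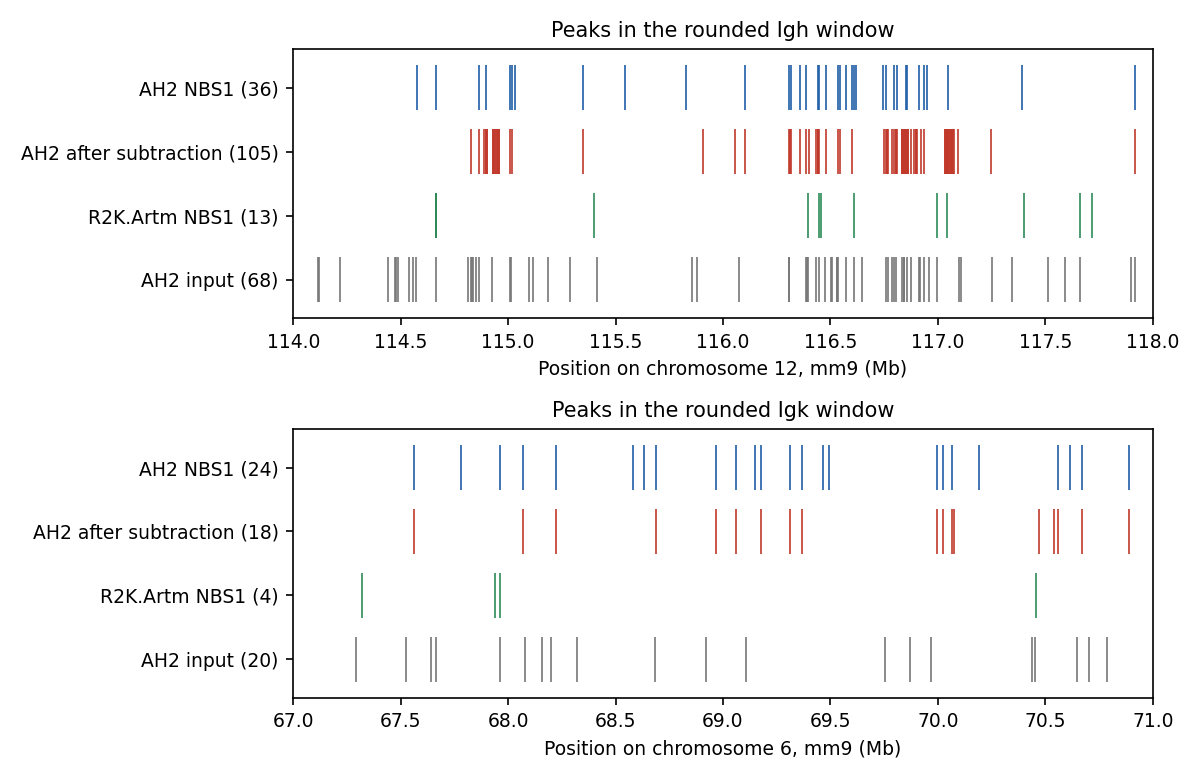
Positions of peaks (1 tick each, at the peak midpoint; horizontal axis in Mb of mm9) in the rounded Igh window on chromosome 12 and Igk window on chromosome 6, with 1 row per list and its number of peaks in brackets. The 105 Igh intervals of the subtracted list crowd into a few places, and its 18 Igk intervals are spread over the window.

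In the immunoglobulin kappa light chain (Igk) window on chromosome 6, also 4 Mb, the subtracted list had 18 intervals, 1.21% (0.766 to 1.90%). AH2 NBS1 had 24 peaks there, 0.461% (0.310 to 0.686%), R2K.Artm NBS1 had 4, 0.125% (0.0487 to 0.322%), and AH2 input had 20, 0.168% (0.109 to 0.259%). The Igk share of AH2 NBS1 was 2.75 times that of input, with intervals apart. It was 3.68 times that of R2K.Artm NBS1, with intervals that overlapped slightly, from 0.310 to 0.322%. Of the 18 intervals, 15 were identical to an AH2 NBS1 peak, and none overlapped an input or an R2K.Artm NBS1 peak. Such overlaps were rare in the whole subtracted list, 6.18% for input and 0.672% for R2K.Artm NBS1, so their absence among 18 intervals says little. The highest-scoring, besides that at 70672652, were at 67560143 to 67560554 (score 155), 69060897 to 69061175 (135) and 68071516 to 68071753 (134). The AH2 NBS1 and subtracted lists exceeded every one of 10000 random windows, whereas the R2K.Artm NBS1 count exceeded 36.9% and the input count 84.1% of them.

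The other 4 loci held few intervals of the subtracted list. The immunoglobulin lambda (Igl) window held 3 intervals of the subtracted list, at 19065569 to 19065651, 19248707 to 19248817 and 19516205 to 19516314 on chromosome 16, beside 3 AH2 NBS1, 1 R2K.Artm NBS1 and 6 AH2 input peaks. The Tcra/Tcrd window on chromosome 14 held 5 intervals of the subtracted list, with scores of at most 59.7, beside 12 AH2 NBS1, 6 R2K.Artm NBS1 and 29 AH2 input peaks. The subtracted-list counts exceeded 96.2% of random windows in Igl and 93.3% in Tcra/Tcrd, and in Tcra/Tcrd the AH2 NBS1 count exceeded 98.3% and the input count 96.1% of them. The Tcrb and Tcrg windows held 0 of the 1489 intervals, which allows a share of up to 0.201% in each (3 counts of the total). AH2 NBS1 itself had 2 peaks in Tcrb and 3 in Tcrg.

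**Figure D3:**
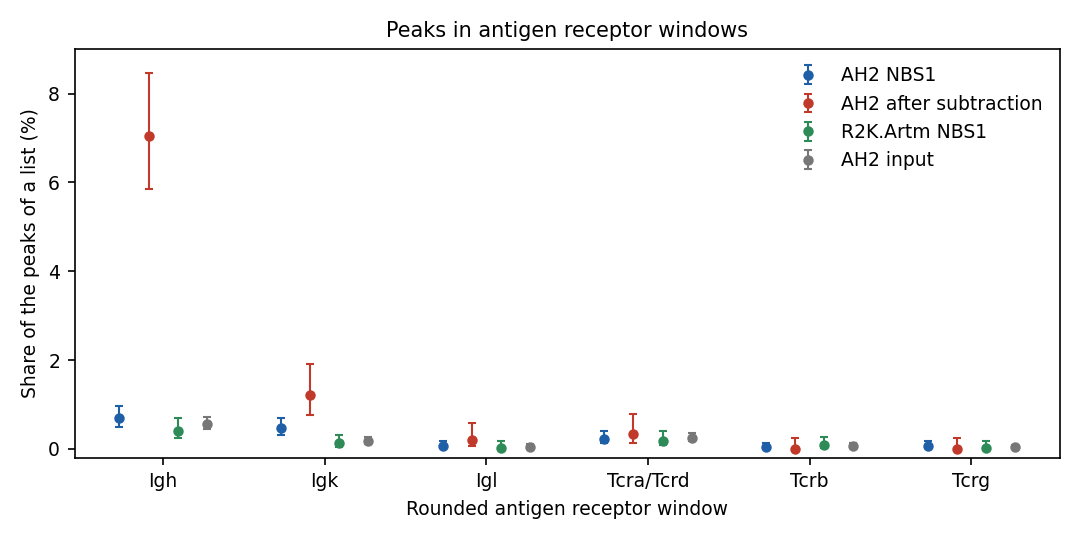
Share of the peaks of each list (vertical axis, percent) in the 6 rounded antigen receptor windows (horizontal axis), with 95% Wilson intervals as bars. The Igh share of the subtracted list, 7.05%, stands above all other values, followed by its Igk share, 1.21%.

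Most of the subtracted list lay outside these loci: 1358 of 1489 intervals, 91.2% (89.7 to 92.5%). Among its 60 intervals with a score of at least 100, 18 were in Igh, 6 in Igk and 36 outside all 6 windows. Of the 60, 23 overlapped an AH2 input peak: 16 of these were outside the windows and the others were in Igh. Chromosome 12 held 10.9% (9.46 to 12.6%) of the subtracted list, against 4.48% of AH2 NBS1, 4.39% of R2K.Artm NBS1 and 4.48% of AH2 input. Outside the 6 windows its share of the subtracted list was 4.27% (3.32 to 5.48%), with the other lists between 3.85% and 4.01%. Chromosome X held 2.15% (1.53 to 3.02%) of the subtracted list, 5.71% (5.11 to 6.37%) of AH2 NBS1, 5.64% (4.89 to 6.49%) of R2K.Artm NBS1 and 3.90% (3.57 to 4.26%) of AH2 input.

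Peaks lay closer together than random placement gave in every list. Another peak of the same list was within 10 kb for 16.5% of AH2 NBS1 peaks (random mean 7.14%), 15.1% of R2K.Artm NBS1 peaks (6.05%), 16.6% of AH2 input peaks (10.3%) and 11.3% of the subtracted list (1.31%). Outside the 6 windows the value for the subtracted list was 5.82% (4.69 to 7.19%), while AH2 NBS1 stayed at 16.6%.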

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

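No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Of 157 alternative values for 41 results, 43 left the 95% interval of the reported share, and the others stayed within it (counts within 1.5 times the reported count). The overlap of AH2 NBS1 with R2K.Artm NBS1 (32.8%) was 34.7% within 1 kb, 55.3% at scores of at least 100, 63.1% between the 1596 top-scoring peaks of each list and 30.1% without chrY, chrM and unplaced sequences. Under coverage of at least 50%, 1 kb, scores of at least 100, equal numbers and placed chromosomes, the overlap with input was 26.8%, 31.3%, 54.1%, 38.9% and 25.6% for AH2 NBS1 and 34.1%, 40.4%, 72.2%, 49.7% and 34.7% for R2K.Artm NBS1. Within 1 kb, 8.87% of the subtracted list was near an input peak. At scores of at least 100 the Igh share was 30% of the subtracted list (18 of 60), 0.224% of AH2 NBS1, 0% of R2K.Artm NBS1 and 0.542% of input. In Igh, AH2 NBS1 was then below input, on 3 peaks. The Igk share was 10% of the subtracted list, 0.448% of AH2 NBS1, 0.111% of R2K.Artm NBS1 and 0.0678% of input. The Igh and Igk excess of the subtracted list was thus larger there, on few intervals. This limit is not alike between lists: 4.03% of the subtracted list reached it, and 25.7% of AH2 NBS1. The Igh share of the subtracted list fell from 7.05% to 2.05% with intervals under 10 kb apart merged, which joins neighbours by construction, and to 2.60% among intervals identical to an AH2 NBS1 peak, which leaves out 81 of the 105. Clustering within 100 kb was 40.3% for AH2 NBS1, 24.8% for the subtracted list, 32.1% for R2K.Artm NBS1 and 63.9% for input, while clustering within 10 kb rose at scores of at least 100 from 16.5% to 22.0%, 11.3% to 28.3%, 15.1% to 22.5% and 16.6% to 22.8% in that order. Outside the 6 windows the share of chromosome 12 was 3.85% for AH2 NBS1, 4.27% for the subtracted list and 3.95% for input. The alternatives for simple sequence repeats, recombination signals, gene lists and gene annotation were not run, as they needed the mm9 sequence or annotation. Where no cause is named, the cause was not tested. Peak lists show only regions past the caller's threshold, so a region with no peak is not shown to lack NBS1.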

Other observations

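All tests below were chosen after the lists had been examined; for merged intervals and for input peaks near Igh intervals, the expected outcome was written before the value was computed. The megabase bins with the most intervals of the subtracted list were 3 bins of Igh on chromosome 12, with 60, 23 and 18 intervals, and the next fullest bin, from 2 Mb of chromosome Y, had 9. The bins with the most peaks in both NBS1 lists were 3 adjacent bins of the unplaced sequence chrUn_random, from 3 to 6 Mb, with 58, 83 and 128 AH2 NBS1 peaks, 47, 65 and 97 R2K.Artm NBS1 peaks and 69, 85 and 133 input peaks, but 0, 0 and 2 intervals of the subtracted list. On placed chromosomes the fullest AH2 NBS1 bin was from 126 Mb of chromosome 8, with 43 AH2 NBS1 and 24 R2K.Artm NBS1 peaks against 12 input peaks and 6 intervals of the subtracted list. The unplaced sequence chrY_random held 2.89% (2.15 to 3.87%) of the subtracted list, against 0.731% of AH2 NBS1, 0.533% of R2K.Artm NBS1 and 0.924% of input. From 4 to 5 Mb of chromosome 14 the subtracted list had 8 intervals, where AH2 NBS1 itself had 4 peaks, R2K.Artm NBS1 had 0 and input had 22.

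The Igh share of the subtracted list (7.05% of intervals) was 2.05% (1.42 to 2.95%) with intervals under 10 kb apart merged. The merged input list had 0.459% (0.347 to 0.606%). This argues against the splitting of zones into pieces under 10 kb apart as the only source of the Igh excess. Splitting of wider zones stays open, because pieces further apart were not joined. By its title, input was subtracted from the list, so these shares do not compare like with like. Regions that gain reads without the antibody stay open. Within 1 kb of an input peak lay 22.9% (15.9 to 31.8%) of Igh intervals, against 7.80% (6.50 to 9.34%) of the other intervals of the list. Igh intervals were thus near input peaks more often, which goes with that explanation but cannot decide it. Input peaks were also denser there, 17 per Mb against 4.08 per Mb on the rest of the chromosome, and crowded Igh intervals can share 1 input peak. Without the intervals that overlap an input peak, the Igh share was 6.44%. The 50% limit set in advance was wrong for a list titled as having input subtracted. In the AH2 NBS1 list without subtraction, 11 of 36 Igh peaks, 30.6%, overlapped input, against 28.9% of the whole list. A difference in the DNA over the locus, such as copy number or strain sequence that maps badly to the reference, is a candidate explanation that stays open: the input list had 68 peaks in the window and at most 30 in any random window of that size. NBS1 at breaks in the Igh locus of AH2 is the biological hypothesis that the design gives, and it was not separated from such a difference, because the lists carry no read depth and no R2K.Artm input was used here.

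The Igk excess was weighed on the AH2 NBS1 list without subtraction as well. Of its 24 Igk peaks, 1 overlapped an input peak, 4.17% (0.739 to 20.2%), against 28.9% (27.7 to 30.1%) of the whole list. This argues against regions called as input peaks as the source of the excess. Low overlap was not particular to Igk, as 0 of 12 AH2 NBS1 peaks in Tcra/Tcrd overlapped input. In the subtracted list 15 of the 18 Igk intervals were identical to an AH2 NBS1 peak, so most were not added by the second peak call. Igk made up 1.63% (0.988 to 2.67%) of the identical intervals, against 0.461% (0.310 to 0.686%) of the whole AH2 NBS1 list. The subtracted list rarely overlaps the other lists, and few Igk peaks did, so this gap can partly follow from the subtraction itself. Without peaks that overlap input, the Igk share of AH2 NBS1 was 0.622% (0.415 to 0.931%). A DNA difference over Igk stays open: the input list had 20 peaks in the window, above 84.1% of random windows but under the highest, 43, and peak lists cannot show an even copy gain. A hypothesis for follow-up is that NBS1 sits at Igk breaks in AH2 and not in R2K.Artm, and replicate libraries and an R2K.Artm input would be needed to test it.

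The subtracted list still held 92 intervals that overlap input peaks, whereas a removal of input peaks as intervals would leave none. Among the 50 highest-scoring intervals 42% (29.4 to 55.8%) overlapped an input peak, against 4.93% (3.93 to 6.18%) of the others. Regions with more DNA reads in AH2 than in R2K.Artm, whatever the antibody, could give this, but overlap with input rises with score in the AH2 NBS1 list too. Of the 50 highest-scoring AH2 NBS1 peaks without an R2K.Artm overlap, 34% (22.4 to 47.8%) overlapped input. Regions with more DNA reads in AH2 could raise that value too, so the comparison cannot decide. The explanation stays open for want of read depth in both lines.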
